A study of Canis lupus familiaris with 6 samples.

How the data were processed

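RNA was sequenced from 6 cultures of canine aortic endothelial cells bought from a supplier and grown in canine endothelial medium with serum. Per the labels' protocols, cells in 24-well plates received polystyrene particles of 100 nm diameter at 25 µg/mL, total RNA was extracted with a DNase step, and libraries were made with a stranded total RNA kit with ribosomal RNA depletion. The series' design text gives the exposure as 48 hours and writes the same dose figure as micromolar; the unit of the treatment protocol is used here. Total RNA libraries of this kind hold non-polyadenylated RNAs as well as messenger RNAs.

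The authors deposited 1 table of raw read counts, with 1 column per library and 30951 Ensembl dog gene identifiers, and replicates were not pooled. Per the submitters' processing notes, the tools were FastQC 0.12.1, Trimmomatic 0.39, STAR 2.7.11a and DESeq2, with the genome build CanFam 3.1. The counting program, the annotation release and the strand setting are not given in the sources used here, so reads shared by overlapping, antisense or near-identical genes cannot be assigned with certainty. Columns were matched to samples by the library names in the labels. There were 11253 identifiers with no count in any library, and 0 rows named anything other than a gene.

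The table holds no gene symbols. The reference table of RefSeq genes (UU_Cfam_GSD assembly) holds 43286 genes, 0 of them with an Ensembl identifier, and 0 of the identifiers matched a symbol. Names were therefore not assigned. The 27 gene lists fixed before the data were examined (endothelial identity, inflammatory, antioxidant, stress, lysosomal, sterol, cell cycle, matrix and other lists, including markers of other cell types) were not tested, and no coordinates are given. Identifiers are printed sparingly: the lowest p in each direction without the block, the lowest p on the lower side with the block, and the DESeq2 call with the lowest p. A further 1, with the largest ratio in a single pair, is given under the additional observations and was chosen after its values were seen. The rule fixed beforehand asked for genes with a symbol and could not be applied as written. Its fallback took the lowest p-values in each direction among identifiers with a mean log2 CPM of 1 or more. It was applied without the symbol, and to 1 identifier per direction and fit rather than the longer list it asked for. On the higher side with the block, the DESeq2 call with the lowest p took the place of the lowest p in edgeR.

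The comparison used edgeR 4.0.16 (quasi-likelihood test, glmQLFit and glmQLFTest) on the deposited counts, with filterByExpr by group (minimum count 10), TMM scaling and a model with the group alone. The 12816 identifiers kept held 99.893% of all counts. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all tested identifiers (12816 in edgeR and limma-voom, 19698 in DESeq2, which was given all identifiers), with a threshold of 0.05. Standard errors are the log2 change divided by the square root of the F statistic. Log2 CPM for correlations, principal components and pair ratios used a prior count of 2. DESeq2 1.42.0 and limma 3.58.1 (voom) were run as alternatives, in R 4.3.3. Intervals of fold changes at 95% are from limma-voom. Library measures were compared by exact permutation tests over the 3 against 3 libraries, and by exact sign flips of the 3 pair differences, added after the data were seen.

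Replicate numbers in the labels pair the samples: the nanoplastics and untreated libraries of 1 number carry the same code in their library names. Deviations from the group means correlated at 0.598, 0.538 and 0.353 for numbers 1, 2 and 3. Libraries of different numbers and groups gave -0.445 to -0.0216. Deviations within a group sum to 0, so positive same-numbered values push the others below 0 and widen this contrast. Without centring, log2 CPM correlated at 0.9874 to 0.9902 for same-numbered libraries. For libraries of different numbers and groups it was 0.9707 to 0.9832. By this measure, the nearest library of each of the 6 was the one with its own number. The fit with the replicate number as a block is given beside the fit without it, since the submitters' notes state no model. As a check for copies of a library, the counts of libraries of 1 group were compared, and the chi-square per degree of freedom was 13 to 32.5 over identifiers with at least 10 counts in both together (5.34 to 7.08 for same-numbered libraries). None was taken for a copy. This does not show that the replicates are independent, since differences in library preparation also exceed counting noise.

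Depth was 12449440 to 15900331 counts per library, and floors from counts cover counting error only. Scripts were tested on simulated counts drawn with the means per replicate number, dispersions and library sizes of the real data, with changes of 1.25, 1.5, 2 and 4-fold in 50 identifiers each per simulation, among those with a mean log2 CPM over 1. Unchanged identifiers called numbered 41 of 63080 for edgeR with the block and 0 without it. Alternatives were DESeq2 size factors or library size alone, other count filters, DESeq2 and limma-voom, the replicate block, and leaving out libraries or pairs. Thinning to equal depth, limma-voom with the block and the checks of replicate numbers and pair ratios were added after the data were seen.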

Results

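Gene expression was measured by RNA sequencing in dog aortic endothelial cells, the cells that line the inside of the aorta, after exposure to polystyrene nanoplastics and in untreated cultures. The 3 nanoplastics libraries came from cells given particles of 100 nm diameter at 25 µg/mL for 48 hours, and the 3 untreated libraries served as controls. The labels do not say whether the replicates came from separate donors or thawed vials, so the p-values measure the spread between these libraries, which may be partly technical. The libraries held 15408411, 14035554 and 12449440 gene counts with nanoplastics and 15900331, 15711104 and 15146592 without, for replicates 1, 2 and 3. A count was present for 16424 to 16843 gene identifiers per library, and 12816 of the 30951 identifiers in the table passed the expression filter and were tested in edgeR and limma-voom. The table lists Ensembl dog gene identifiers without symbols, and no identifier could be matched to a symbol, so the results below are given for identifiers and not for named pathways.

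The comparison of nanoplastics-treated with untreated endothelial cells, for which the series was designed, gave no called identifier without a block for replicate number, and 3 higher in DESeq2 with the block. In edgeR's quasi-likelihood test without the block and with Benjamini-Hochberg adjustment, 0 of 12816 identifiers were higher and 0 were lower, and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 114 identifiers, against 641 that a uniform distribution of p-values would give. Limma-voom on the same identifiers called 0, with 112 at an unadjusted p under 0.05. DESeq2 without a block, run on the 19698 identifiers with a count in any library, also called 0, with 96 against 985 for a uniform distribution.

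The libraries grouped by replicate number and not by treatment. On the first 2 principal components of log2 CPM (counts scaled to the TMM-adjusted library total), which held 44.9% and 22.8% of the variance, each treated library lay beside the untreated library of the same number. Same-numbered libraries correlated at 0.9874 to 0.9902 across tested identifiers, while libraries of the same group but different numbers correlated at 0.9722 to 0.9818. Of the sum of squares of log2 CPM over all tested identifiers, 67.5% lay between the 3 replicate numbers (2 degrees of freedom), 10.8% between treated and untreated (1 degree of freedom) and 21.8% in the remainder (2 degrees of freedom). Per degree of freedom this was 33.8% for replicate number, 10.8% for treatment and 10.9% for the remainder.

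**Figure D1:**
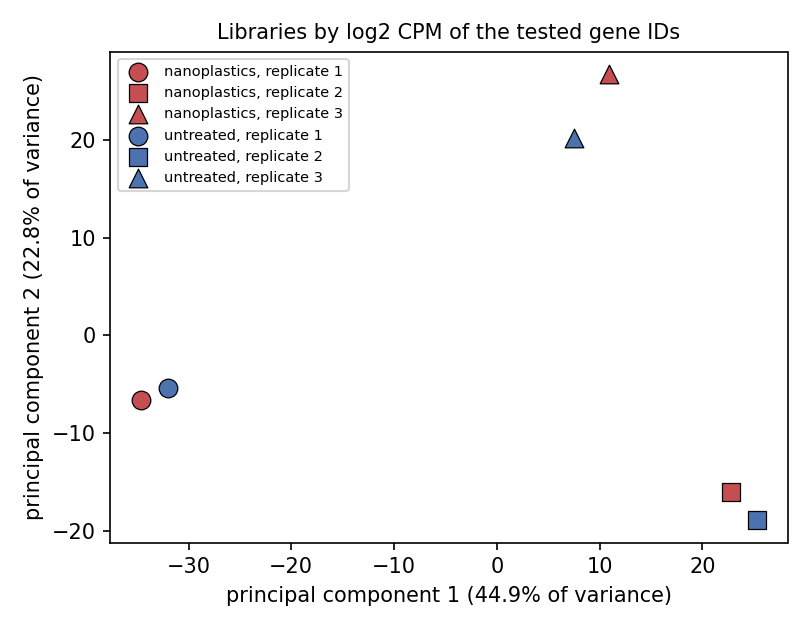
Scores of the 6 libraries on principal components 1 and 2 of log2 CPM over the tested gene identifiers, with the share of variance on each axis. Colour marks the group and marker shape the replicate number. The 2 libraries of each replicate number lie close together, and the 3 replicate numbers lie apart.

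Expression differed between the replicate numbers in 2701 of 12816 identifiers (21.1%; edgeR quasi-likelihood test of replicate number with treatment in the model, Benjamini-Hochberg adjusted p under 0.05). Between numbers 1 and 2, 1222 identifiers were higher in number 1 and 1124 were lower, and 531 of these differed by at least 2-fold. Between numbers 1 and 3 there were 911 higher and 891 lower in number 1, with 422 at 2-fold or more. Numbers 2 and 3 were closest, with 456 higher and 480 lower in number 2 and 176 at 2-fold or more.

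Because treated and untreated libraries of one number varied together, the comparison was repeated within pairs, with the replicate number as a block. The common biological coefficient of variation was 19.1% without the block and 7.56% with it. With the block, edgeR again called 0 identifiers higher and 0 lower, with a smallest adjusted p of 0.1608 and 491 identifiers at an unadjusted p under 0.05. Limma-voom with the block called 0 (smallest adjusted p 0.07967, 478 at an unadjusted p under 0.05). DESeq2 with the block called 3 higher and 0 lower, each of the 3 at an adjusted p of 0.01588, with 125 of 19698 at an unadjusted p under 0.05.

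The 3 identifiers called higher in the blocked DESeq2 test changed by small amounts and were higher in 3 of 3 pairs. ENSCAFG00000042795, the one with the smallest p, was at 211.9 ± 55 CPM with nanoplastics and 168.2 ± 41.6 CPM without (SD, n = 3 each). Its DESeq2 log2 change was 0.33 with a standard error of 0.07, while edgeR with the block gave an adjusted p of 0.1608 and edgeR without it 0.9999. The other two stood at 143.8 ± 40.9 against 104.8 ± 20.5 CPM and at 5055 ± 638 against 4340 ± 662 CPM (SD, n = 3 each), with DESeq2 log2 changes of 0.44 ± 0.09 and 0.23 ± 0.05 (standard error). These identifiers were singled out after their values were seen. With the treatment labels swapped inside pair 1, 2 or 3, the same test called 8, 0 and 2 identifiers, so the 3 calls may be chance.

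Outside those calls, the identifiers with the lowest p-values did not pass in any of the fits of the deposited counts on all 6 libraries. ENSCAFG00000042712 had the smallest p without the block. It was measured at 6.23 ± 1.1 CPM with nanoplastics and 2.98 ± 0.565 CPM without (SD, n = 3 each), from 38 to 93 counts per library. Its log2 change was 1.06 with a standard error of 0.25, with an edgeR adjusted p of 0.9999 without the block and 0.6647 with it. On the lower side, ENSCAFG00000025373 was at 5.88 ± 1.47 CPM with nanoplastics and 9.75 ± 0.48 CPM without (log2 change -0.72, standard error 0.21, edgeR adjusted p 0.9999). ENSCAFG00000032630, which had the smallest p on the lower side with the block, was at 51.5 ± 2.39 and 63.5 ± 6.19 CPM (blocked log2 change -0.30, standard error 0.07, edgeR adjusted p 0.9998).

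**Figure D2:**
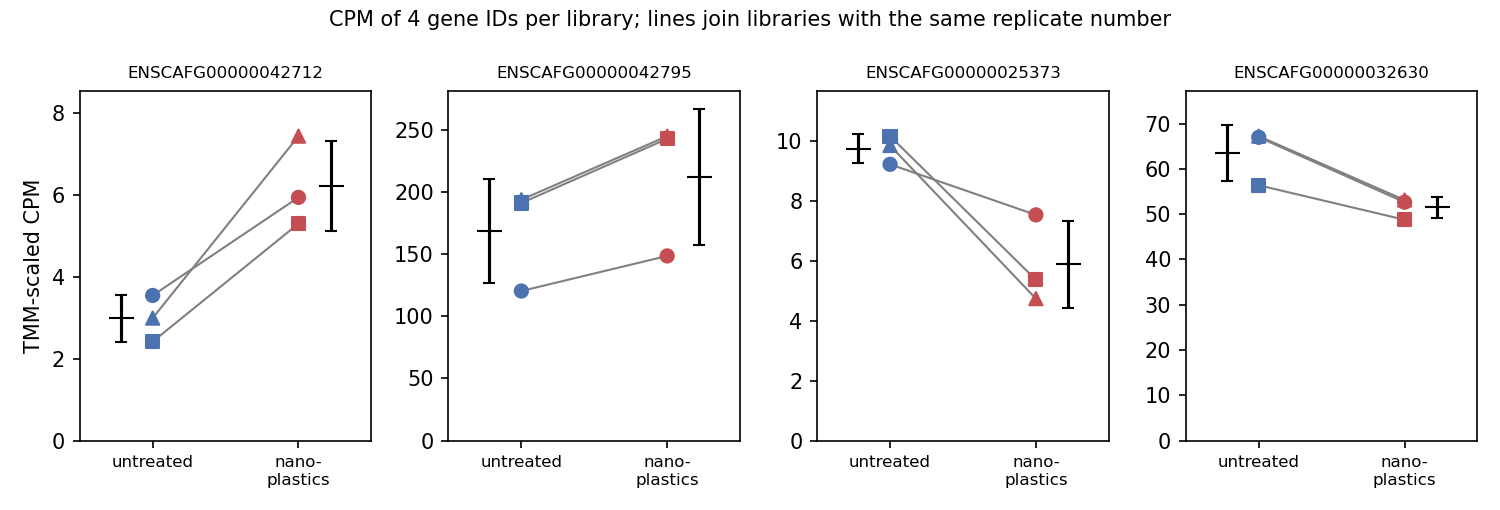
TMM-scaled CPM of 4 gene identifiers in each untreated and nanoplastics library, with grey lines joining libraries of the same replicate number and marker shape giving the number. Black bars beside the points are the group mean ± SD (n = 3), and each vertical axis starts at 0. All 3 lines run upward in the panels on the left and downward in those on the right, while the 2 groups of ENSCAFG00000042795 overlap.

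The differences between treated and untreated cells correlated weakly or not at all from one pair to the next. Across the 12816 identifiers, the treated-to-untreated log2 ratios of pairs 1 and 2 correlated at r = 0.00742 (Spearman's rho 0.00463), those of pairs 1 and 3 at -0.00681 (rho -0.061) and those of pairs 2 and 3 at -0.0122 (rho 0.0172). These correlations run across genes, which are not independent replicates, and the pairs have no library in common. Counting noise is lower among the 5319 identifiers with a mean log2 CPM of 5 or more. There r was 0.0442, -0.199 and 0.0938 for the same 3 combinations (rho 0.00596, -0.197 and 0.0807). A single identifier, with log2 ratios of 1.52 in pair 1 and 4.28 in pair 2, weighs on the first r. The direction was the same in all 3 pairs for 3024 identifiers (23.6%), of which 1427 were higher and 1597 lower with nanoplastics, against 25% by chance. The 3 treated and 3 untreated libraries did not overlap for 608 identifiers (4.74%). The 3 other ways of splitting the libraries with 1 of each pair on either side gave 578 to 715 (4.51% to 5.58%).

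**Figure D3:**
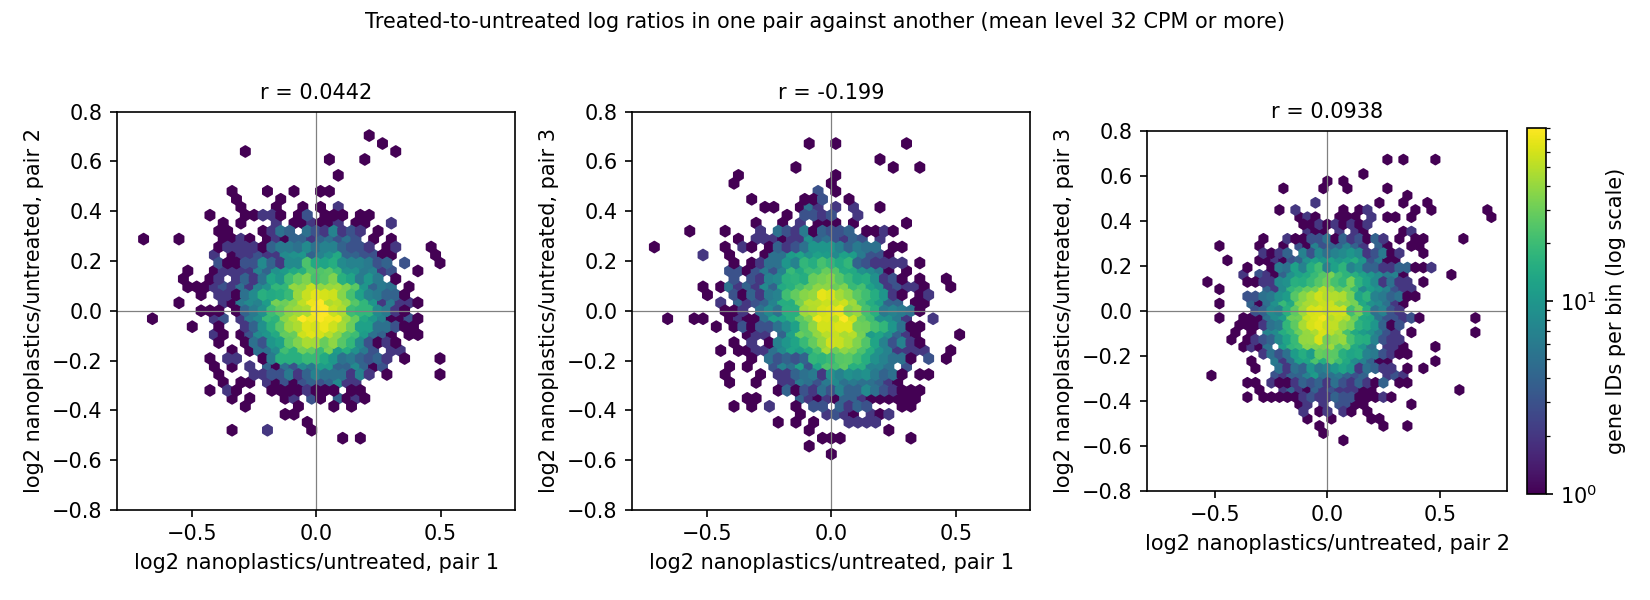
Log2 ratio of nanoplastics to untreated CPM in one same-numbered pair against another, for the 5319 gene identifiers with a mean log2 CPM of 5 or more; colour gives the number of identifiers per bin on a log scale. The axes end at 0.8 in both directions, and 8 identifiers lie beyond that in at least 1 pair. The clouds are centred near 0, with r of 0.0442, -0.199 and 0.0938 (Spearman's rho 0.00596, -0.197 and 0.0807). These values include the identifiers beyond the axes.

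For well-expressed genes the intervals of the fold change were narrow. In limma-voom with the block, the 95% interval of the fold change lay within 2-fold in either direction for 11229 of 12816 identifiers (87.6%) and within 1.5-fold for 9521 (74.3%). Among the 5319 with a mean log2 CPM of 5 or more, 5318 lay within 2-fold and 5311 within 1.5-fold. Without the block these were 5252 and 5047. In data simulated with the spread and depth of these libraries, with 200 of 12816 identifiers changed in each of 5 simulations, edgeR with the block called 93.6% of identifiers changed 2-fold, 75.2% of those changed 1.5-fold and 34.4% of those changed 1.25-fold. Without the block it called 55.6%, 7.6% and 0%. The identifiers changed in these simulations all had a mean log2 CPM over 1, so detection at lower levels was not measured. Each identifier was drawn independently, so shifts shared by many identifiers within a real pair were not simulated. The adjusted p also depends on how many identifiers change. These shares hold for 200 changed identifiers and need not hold for a response of a few. In limma-voom with the block the 95% interval reached a median of 1.94-fold to either side for the 1534 identifiers with a mean log2 CPM under 1 and 1.11-fold for the 5319 with 5 or more. A total of 3 counts corresponds to 0.189 to 0.241 CPM in the individual libraries.

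**Figure D4:**
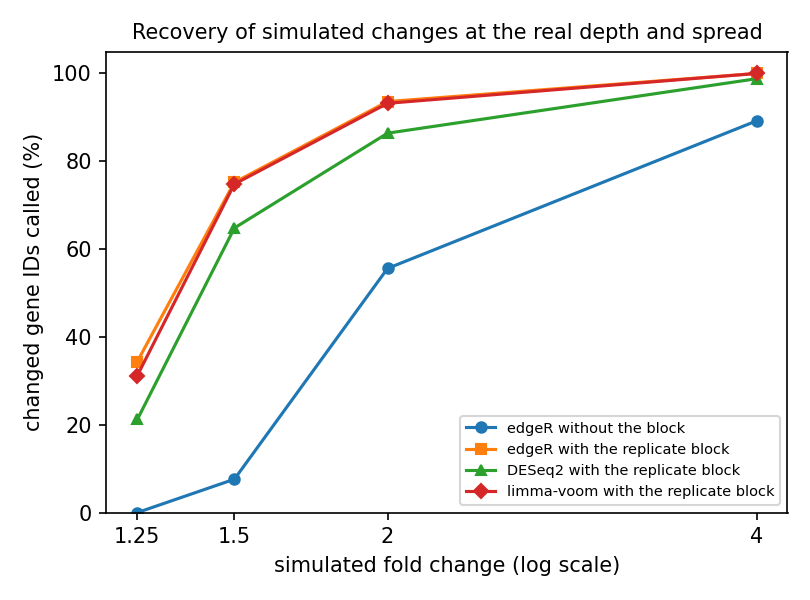
Share of simulated changed gene identifiers called at an adjusted p under 0.05 (vertical axis, percent) by simulated fold change (horizontal axis, log scale), for edgeR without the block and for edgeR, DESeq2 and limma-voom with it. Each point pools 250 identifiers over 5 simulations. At 2-fold the share is 55.6% for edgeR without the block and 93.6% with it.

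Library make-up was compared on 4 measures, and 3 of them shifted in the same direction in all 3 pairs. Total counts were 13964468 ± 1480766 with nanoplastics and 15586009 ± 392132 without, lower with nanoplastics in 3 of 3 pairs (exact permutation test, two-sided p = 0.2, Benjamini-Hochberg adjusted over 4 measures 0.4). Identifiers with a count numbered 16630 ± 195 and 16706 ± 125 (exact p = 0.6, adjusted 0.6). The 10 most abundant identifiers took 12.64 ± 0.507% and 12.16 ± 0.984% of counts, higher with nanoplastics in 3 of 3 pairs (exact p = 0.5, adjusted 0.6). The single most abundant identifier took 3.87 ± 0.386% and 3.25 ± 0.671% (exact p = 0.2, adjusted 0.4). Because it belongs to the 10 most abundant, its share is part of theirs, and these measures are not separate shifts. It was higher with nanoplastics in 3 of 3 pairs, with a blocked log2 change of 0.28 (standard error 0.05) at an adjusted p of 0.373 in edgeR and 0.0591 in DESeq2. All errors are SD with n = 3, and a test of 3 libraries against 3 cannot give a p under 0.1. These tests do not use the pairing. In an exact paired permutation test (sign flips within pairs, two-sided), the 3 measures that shifted in 3 of 3 pairs each had p = 0.25 (adjusted 0.333), the lowest that 3 pairs can give, and the number of identifiers with a count had p = 0.75 (adjusted 0.75).

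A few identifiers were detected in 1 group only. There were 2 with at least 3 counts in every nanoplastics library and none in any untreated library, and 6 with the reverse. The other 18 choices of 3 of the 6 libraries gave 1 to 6 such identifiers, with a median of 2.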

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

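Of 27 alternatives to the comparison of nanoplastics with untreated cells, 22 gave 0 identifiers in both directions, among them other scalings, other count filters, limma-voom, DESeq2 without the block, edgeR with the replicate block, and leaving out each library or each replicate number without the block. Unadjusted p-values under 0.05 numbered from 67 to 834 over these alternatives, which do not all test the same set of identifiers. Every alternative without the block gave 0, and the 5 that called an identifier all used it. The 22 are thus mostly refits without the block, and edgeR without it called 7.6% of 1.5-fold changes in the simulations. Among them, a 2-fold cut and a threshold of 0.1 on the edgeR fit without the block could only give 0. The smallest adjusted p of that fit was 0.9999. With the replicate block, DESeq2 gave 3 higher. Leaving out pair 1 in the blocked edgeR fit gave 37 higher and 4 lower, and leaving out pair 2 gave 1 higher. These fits on 4 libraries have 1 residual degree of freedom. The one without pair 1 gave identifiers of like level the same spread, with no estimate of their own. Swapping the treatment labels inside 1 of the remaining pairs gave 8, 34 and 6 calls without pairs 1, 2 and 3, against 41, 1 and 0 with the true labels. Thinning every library to the smallest total, chosen after seeing the data, gave a median over 10 random draws of 4 higher with the replicate block in edgeR (range 0 to 9), of 3 higher with the block in DESeq2 (range 0 to 3), and 0 without the block; the cause was not tested. None of the 22 alternatives run for the 4 identifiers named, which leave out the thinned fits, reversed a change: their log2 changes ranged from 0.91 to 1.23 for ENSCAFG00000042712, from 0.14 to 0.53 for ENSCAFG00000042795, from -0.99 to -0.58 for ENSCAFG00000025373 and from -0.38 to -0.26 for ENSCAFG00000032630. Without pair 1 the blocked edgeR fit called the first 3 of these. The 4 identifiers were picked for low p-values in these same libraries, and each kept 1 direction in all 3 pairs. A reversal was therefore unlikely from the start, and its absence is no support for the changes. The number of identifiers differing between replicate numbers stayed within 1.5 times of 2701 in 8 alternatives. The mean correlation of pair log ratios was -0.00387 and lay at -0.0205 for identifiers with a mean log2 CPM of 5 or more. Gene list tests under every planned setting were not run, since identifiers had no symbols. Detection at low counts was not simulated, and small changes were often missed in the simulations.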

Other observations

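The comparison of the groups with edgeR and with DESeq2, with and without the block, was planned; the test of replicate numbers, the correlation of deviations, the thinning, the removal of abundant identifiers and the splits counted with edgeR were chosen after the data were seen.

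Among identifiers with a mean log2 CPM of 5 or more, 1 had the largest ratio in 2 of the 3 pairs. ENSCAFG00000028987, chosen after its values were seen, was at 416.2 CPM in nanoplastics replicate 2 and 21.3 CPM in untreated replicate 2, a ratio of 19.4-fold and the largest of any of them. In pair 1 the ratio was 2.87-fold (81.7 and 28.4 CPM), the largest in that pair, and in pair 3 it was 1.07-fold (120.4 and 112.3 CPM). Its blocked log2 change was 1.86 with a standard error of 0.49 and an edgeR adjusted p of 0.9998. Apart from it, ratios of 2-fold or more in a single pair were rare among the 5319 well-expressed identifiers: the totals, this one included, were 1 higher and 1 lower in pair 1, 2 higher in pair 2, and 2 higher and 1 lower in pair 3.

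The replicate numbers differed in 2701 identifiers. Unequal depth would lower that count once the libraries are brought to equal totals, and it came to 2909 after a random thinning. The differences thus did not need unequal totals. The fit already scales each library, and random thinning keeps the scaled ratios of well-counted identifiers. A large fall was therefore unlikely from the start, and anything else that goes with depth was not tested. A few abundant identifiers taking counts would lower it once they are removed, and it was 2681 without the 50 most abundant. TMM scaling is meant to offset such a shift before the test, so a large fall was unlikely here as well. This count therefore decides nothing about that explanation. The lowest same-numbered correlation of deviations, 0.353, restates the pattern and does not support any source of it. The labels do not state what the code shared in the library names marks, so a batch of culture and a batch of library preparation stay open, and no biological explanation was tested.

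The comparison without the block gave fewer low p-values than a uniform distribution would, 114 against 641. A candidate explanation is that the replicate-number differences sit inside both groups and inflate their spread. The 4 splits of the 6 libraries that separate every pair gave 89 to 142 identifiers at an unadjusted p under 0.05, and the 6 splits that keep a pair together gave 618 to 1860. Splits that keep a pair together carry the replicate-number differences into the contrast, so this outcome follows from the grouping already seen and decides nothing. The block takes these differences out, and with it the common biological coefficient of variation fell from 19.1% to 7.56%. EdgeR with the block gave 491 identifiers at an unadjusted p under 0.05, more than 114 but still below 641. With the block, the other splits that separate every pair gave 434, 669 and 840 in edgeR, on both sides of 641. The real 491 lies within that range, so these counts do not show that a shortfall remains once the block is used. How large a part of the shortfall the explanation covers stays open. Without the block, none of the 10 splits called an identifier at an adjusted p under 0.05. The real value was 0 and the highest of the others was 0. A count of 0 is reached by every split, so this says nothing about chance, and with 10 splits a share under 0.05 cannot be reached.

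The 3 identifiers called by DESeq2 with the block may be small changes or chance. After thinning every library to the smallest total, all 3 were still called in 8 of 10 draws and none in 1 draw. In those 8 draws the calls did not need unequal totals. The log2 changes of the 3 stayed within 1 standard error of the values before thinning, at 0.32 to 0.34 for ENSCAFG00000042795 against 0.33. Random thinning keeps the scaled ratios of well-counted identifiers, so this stability was fixed in advance. Anything else that goes with the lower totals of the nanoplastics libraries was not tested. Among the 4 splits that separate every pair, 2 gave at least as many DESeq2 calls, the real one included, and the highest of the other splits gave 8 against the real 3. With 4 splits a share under 0.05 cannot be reached. With edgeR and the block the real count was 0, which all 4 splits reach whatever the data, so that count decides nothing; the highest of the others was 10.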
